A study of Homo sapiens with 6 samples.

How the data were processed

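Samples were taken from the sample labels: scramble, sh528 and sh529, 2 arrays each, all from MCF10A cells. Per the protocols in the labels, cells grown in DMEM/F12-based medium were stably transduced with hairpin vectors, total RNA was isolated on columns, and biotin-labeled RNA was hybridized. The sequences of the hairpins, and what the replicate number marks (a culture or a transduction, for example), are not given in the sources used here. The p-values therefore measure the spread between these samples, which is technical if the replicates share a culture. Of the scanner values deposited for 7 arrays, 1 array (4 columns) belongs to no sample of the series and was not used. The signal columns hold intensity per the file headers. The detection p-value per the file headers is the p-value of a probe against the negative controls. The authors deposited a matrix on a log2 scale for 24702 probes, and it equals the log2 of the quantile-normalized signal to within 0.0028.

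All 6 arrays lay on 1 BeadChip. Of 47323 probes, 93 were controls, 35756 were named through a gene number or accession and 11474 kept the name in the file, with 8839 symbols updated. Probes carried a median of 22 beads, with a median bead SE of 5.14 to 5.93% of the signal. Signal was background-corrected with normexp using the detection p-values (offset 16), quantile-normalized and put on log2 (neqc of limma 3.58.1, R 4.3.3, data.table version 1.17.8). Probes were kept if detected at 0.05 on at least 2 of 6 arrays (19649 probes), and 1 probe per gene, that with the highest mean, was kept (15055 genes, of which 3572 had more than 1 probe and 2483 a provisional name). Linear models with 3 groups were fitted in limma with an intensity trend in the prior (3 residual and 7.46 prior degrees of freedom). The contrasts were the mean of both hairpins against scramble, each hairpin against scramble, and sh529 minus sh528. Calls used a Benjamini-Hochberg adjusted p of 0.05. By chance 753 genes would reach an unadjusted p of 0.05 in each contrast. The median SE was 0.23 for both hairpins and 0.26 for the other contrasts; the self-test gives what this number of arrays can recover. Median absolute differences between replicates were 0.26, 0.27 and 0.26.

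Gene lists (36, of which 5 hold markers of other cell types, 1097 entries, all matched to the annotation) were written before the data were examined, as were the contrasts, the cutoffs and the alternatives. Lists were tested with camera at a preset correlation of 0.01, with an estimated correlation and fry as alternatives. Where a group was not detected on any array, its level was set to the lowest detected log2 intensity of each array (4.88 to 4.93) and the fold was given as "at least". Named genes were HOXA5, CDH1 and CD24; the 12 largest rises and 12 largest falls over both hairpins, and the 5 largest each way in the other contrasts, among called genes whose groups did not overlap; and up to 4 members with the smallest p per list described. Provisional names were counted but not named, and not every gene the rule picks is printed. Genes outside this rule are said to have been chosen after their values were seen.

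Whether equal replicate numbers pair across groups was checked on the difference of replicate 2 from replicate 1. These differences correlated by 0.27 (scramble and sh528), 0.33 (scramble and sh529) and 0.38 (sh528 and sh529), and the second principal component (26.2% of variance, against 35.4% for the first) split the numbers. By the criterion set, the numbers pair, but 3 differences point the same way by chance 25% of the time and the labels do not say what the number marks. Results were therefore given without the number in the model, with values from a fit that holds it (2 residual and 14.5 prior degrees of freedom) beside them where they matter.

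A self-test added known changes to 200 of 15055 genes in 20 simulations with the spread of these arrays. At a log2 change of 0.5, 1 and 2 the share recovered was 5.52, 61.0 and 100% for both hairpins and 3.43, 42.2 and 99.6% for a single hairpin against scramble (sh528), with 7.61 and 8.39% false calls for these 2 contrasts. A list shift of -0.2 was called in 20 of 20 simulations, and of the 35 unshifted lists 0.1 were called on average. Each gene was drawn independently, so the simulated lists lacked the correlation between real genes. That correlation was estimated at 0.41 for cholesterol and fatty acid synthesis and 0.43 for unfolded protein and amino acid stress. The self-test therefore gives no rate of false calls for lists whose members move together. Alternatives varied the background correction, normalization, source of values, filter, choice of probe, prior, arrays in the fit, replicate block and cutoff, and each array was left out in turn of the fit, keeping the normalization of all 6. With 1 array left in a group, that sample is assumed to vary like the other groups. Lists that hold HOXA5 were also tested without it, and the correlation and shared signs of the hairpins were set beside simulations with no change that keep the shared scramble arrays, and each hairpin was set against a different scramble array. These checks were added after the results were seen. A BeadChip block was not run, since there was 1 BeadChip. Probe coordinates were used for cytobands only, since their build is not given in the sources used here. Tables and figures used Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.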

Results

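MCF10A is a human mammary epithelial line that is immortal but does not form tumors. RNA was taken from cells stably transduced with a scrambled hairpin (2 arrays), with the HOXA5 hairpin sh528 (2 arrays) or with the HOXA5 hairpin sh529 (2 arrays). It was measured on an Illumina expression BeadChip. In array order (scramble 1 and 2, sh528 1 and 2, sh529 1 and 2) the median signal was 104.4, 103.5, 99.4, 98.8, 100.8 and 102.3. In the same order 17708, 18220, 18265, 17594, 17730 and 18190 of 47230 non-control probes were detected. After the detection filter 15055 genes were tested. Values are log2 changes against scramble with the standard error (SE). Adjusted p is over all 15055 genes, or over all 36 gene lists where a list is tested. Arrays that carry the same replicate number resembled each other. Values from a fit that also holds the replicate number (replicate block) are therefore given where they change a call or move a count by more than 1.5-fold.

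HOXA5, the targeted homeobox gene at 7p15.2, was detected in every group and fell in the cells with either hairpin. Its log2 intensity was 10.47 and 9.75 on the scramble arrays, 8.10 and 7.99 with sh528 and 8.94 and 8.52 with sh529, so all 4 knockdown arrays lay below both scramble arrays. HOXA5 fell 3.30-fold over both hairpins (log2 change -1.72 ± 0.23, adjusted p = 0.0220) and 4.19-fold with sh528 (-2.07 ± 0.27, adjusted p = 0.00572). With sh529 HOXA5 was 2.6-fold lower on both arrays, which did not pass (-1.38 ± 0.27, adjusted p = 0.215, 0.00105 with the replicate block). Both sh529 arrays had more HOXA5 than both sh528 arrays, a difference that did not pass without the replicate block (sh529 minus sh528 0.69, adjusted p = 0.387, 0.0484 with the replicate block). The scramble arrays themselves lay apart, and without scramble replicate 1 the HOXA5 change was -1.36 (adjusted p = 0.308) for both hairpins and -1.71 (adjusted p = 0.0558) for sh528. HOXA5 over both hairpins also missed the cutoff when the spread was modeled without an intensity trend (adjusted p = 0.0693, with a range of 1.39e-05 to 0.0693 over the alternatives that keep all 6 arrays). The other measured HOXA cluster genes, such as HOXA6 (-0.49, adjusted p = 0.669) and HOXA9 (-0.33, adjusted p = 0.759), did not pass alone.

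**Figure D1:**
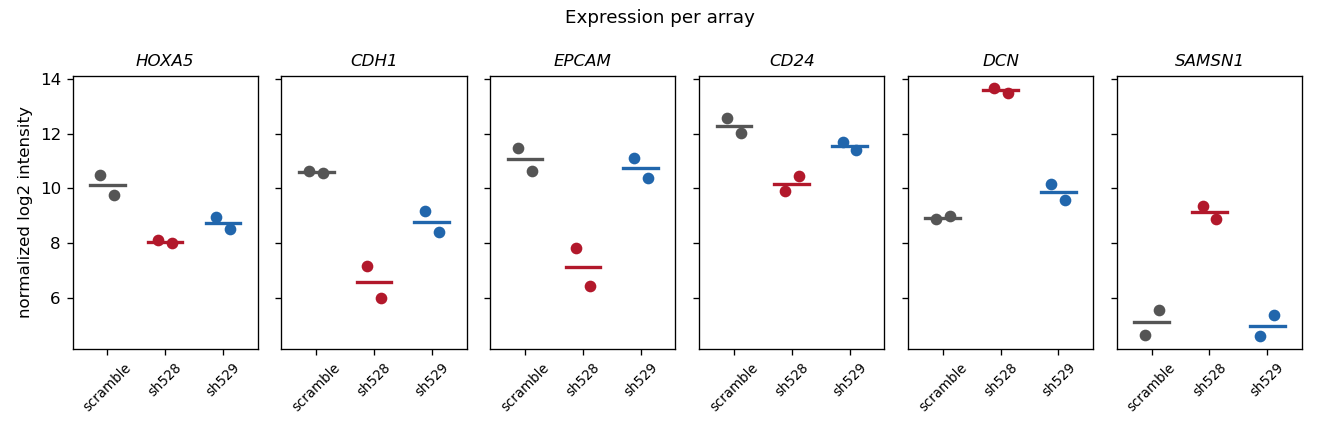
Normalized log2 intensity of HOXA5, CDH1, EPCAM, CD24, DCN and SAMSN1 on each of the 6 arrays (points), with the group mean as a line. HOXA5 means were 10.11 (scramble), 8.04 (sh528) and 8.73 (sh529).

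Over both hairpins, genes of epithelial adhesion fell as a list (adjusted p = 1.12e-27, adjusted p = 0.211 with an estimated correlation). The largest single changes were the fall of CDH1 and the rise of DCN. Of 15055 genes, 16 were higher and 19 lower (185 and 218 with the replicate block), and in 33 of these 35 all 4 knockdown arrays lay on 1 side of both scramble arrays. This contrast averages the hairpins, so a gene can pass it mainly through sh528. CDH1, the gene of E-cadherin, fell 7.53-fold (-2.91 ± 0.31, adjusted p = 0.00649). MAL2, of apical transport, fell 4.61-fold (-2.20, adjusted p = 0.0364), but with sh529 alone it stood at -0.56 (adjusted p = 0.933). ALDH1A3, which makes retinoic acid, fell 3.75-fold (-1.91, adjusted p = 0.0220). HES2, a basic helix-loop-helix repressor, fell 3.91-fold (-1.97, adjusted p = 0.00649) and the calcium-binding S100P fell 4.18-fold (-2.06, adjusted p = 0.00649). Lower as well were the p38 kinase gene MAPK13 (-1.76, adjusted p = 0.0277), the tight junction gene CGN (-1.68, adjusted p = 0.0363) and the protease inhibitor PI3 (-1.52, adjusted p = 0.0220). The desaturase SCD5 also fell (-1.55, adjusted p = 0.0326, -0.40 on its weaker probe), and with sh529 alone it stood at -0.74 (adjusted p = 0.754). CD24, a surface glycoprotein gene with near-identical copies in the genome, was lower on both of its probes (-1.44 and -1.95, adjusted p = 0.0277). OCLNP1, a copy of the occludin gene, was lower as well (-1.88, adjusted p = 0.0110), but its probe cannot be assigned to 1 copy with certainty.

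Among the rises, DCN, the matrix proteoglycan decorin, rose 6.95-fold (2.80 ± 0.18, adjusted p = 0.000233, 1.46 on its weakest probe) on all 4 knockdown arrays. DYNLRB1, a dynein light chain, rose 3.19-fold (1.67 ± 0.15, adjusted p = 0.00384), with 1.67 to 1.88 on its 4 probes. The aldo-keto reductase AKR1C2, which reduces steroids, rose 4.23-fold on 1 probe (2.08, adjusted p = 0.0220) and by 0.22 on the other. Its paralog AKR1C4 rose 3.0-fold (1.59, adjusted p = 0.0277). Which member of this family moved is uncertain. The fatty acid hydroxylase CYP4V2 rose 3.75-fold (1.91, adjusted p = 0.0220) and the mitochondrial dehydrogenase HSD17B10 rose 3.55-fold (1.83, adjusted p = 0.0235). IFI44L, an interferon-induced gene, was not detected in scramble and rose at least 2.83-fold (adjusted p = 0.0277). With sh529 alone IFI44L stood at 0.58 (adjusted p = 0.860) and was detected on 1 of 2 arrays. The granule protein gene CHGB rose at least 2.25-fold (adjusted p = 0.0375). A smaller rise was seen in the anticoagulant protein S gene PROS1 (1.42, adjusted p = 0.0363). The collagen-binding integrin gene ITGA10 (1.40, adjusted p = 0.0336) and the NOTCH ligand gene DNER (1.39, adjusted p = 0.0277) rose likewise. Without scramble replicate 1 only 1 gene was higher and 0 lower. In that fit DCN alone of the 24 genes with the largest changes stayed called (CDH1 adjusted p = 0.127, CD24 0.340). Without scramble replicate 2 it was 4 of the 24, without sh528 replicate 1 or 2 it was 18 or 16, and without sh529 replicate 2 it was 22. With the spread modeled without an intensity trend 6 of the 24 stayed called. With the mean of a gene's probes AKR1C2 and SCD5 lost their calls, with the robust prior AKR1C2 and MAL2, with strict detection MAL2. CHGB lost its call without background correction, at offset 50 and from the deposited matrix. The counts were 3 and 4 without scramble replicate 2 and 8 and 24 without sh528 replicate 1. Without sh528 replicate 2 they were 12 and 10, and without sh529 replicate 1 they were 26 and 29.

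Genes of epithelial adhesion and polarity fell as a group, with 26 of 27 lower (median -1.06, adjusted p = 1.12e-27, adjusted p = 0.211 with an estimated correlation). Of these 4 were called lower over all genes (18 with the replicate block) and 20 when adjusted over the list alone. CDH1, MAL2, CGN and CD24 were the 4 called members. EPCAM, the epithelial cell adhesion molecule, was lower by 2.12 without passing (adjusted p = 0.0619, 1.20e-06 with the replicate block), and its sh529 and scramble arrays overlapped. Desmosome and hemidesmosome genes fell too, with 17 of 19 lower, 0 called over all genes (5 with the replicate block) and 6 lower adjusted over the list alone (median -0.55, adjusted p = 3.79e-07, adjusted p = 0.211 with an estimated correlation). Examples that did not pass alone were the plakoglobin gene JUP (-0.78, adjusted p = 0.199, 0.0133 with the replicate block) and the cadherin DSG3 (-1.61, adjusted p = 0.233, 0.000331 with the replicate block). Keratinocyte differentiation genes fell, 17 of 22 lower, S100P and PI3 being the 2 called (7 with the replicate block, median -0.41, adjusted p = 1.39e-06, adjusted p = 0.211 with an estimated correlation). Luminal epithelial genes fell, 12 of 16 lower, with ALDH1A3 and CD24 called (5 lower and 1 higher with the replicate block) and the luminal transcription factor FOXA1 at -1.14 (adjusted p = 0.0803, 0.00337 with the replicate block). The luminal median was -0.44 (adjusted p = 5.54e-05, adjusted p = 0.211 with an estimated correlation). Basal and myoepithelial genes were lower in 17 of 23, 0 called (8 with the replicate block, median -0.35, adjusted p = 0.00381, adjusted p = 0.412 with an estimated correlation), led by the keratin gene KRT16 (-0.96, adjusted p = 0.0665, 0.00163 with the replicate block). Without scramble replicate 2 the basal list missed the cutoff (mean -0.31, adjusted p = 0.0502).

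Retinoic acid response genes fell, 13 of 19 lower, with ALDH1A3 and HOXA5 itself the 2 called lower (3 lower and 1 higher with the replicate block, median -0.13, adjusted p = 0.00267, adjusted p = 0.211 with an estimated correlation). Without HOXA5 the list still passed (mean -0.24, median -0.13, adjusted p = 0.0169, adjusted p = 0.311 with an estimated correlation). ALDH1A3 stays in it and is also in the luminal list, which shares CD24 with the epithelial adhesion list. The falls of these lists are therefore not fully separate evidence. HOXA cluster genes were lower in 6 of 8 (median -0.34, adjusted p = 0.00328, adjusted p = 0.509 with an estimated correlation). HOXA5 itself is a member, and without it the other 7 had a mean of -0.25 and did not pass (adjusted p = 0.0587). The call on all 8 was also lost without scramble replicate 1 (mean -0.23, adjusted p = 0.230). Mitosis genes were lower by a little in 43 of 46, such as the kinetochore gene NUF2 (-0.71, adjusted p = 0.299, 0.0311 with the replicate block) and the spindle checkpoint kinase BUB1 (-0.40, adjusted p = 0.548). None passed alone (1 with the replicate block), while the list did (median -0.17, adjusted p = 1.69e-05, adjusted p = 0.211 with an estimated correlation). DNA replication genes were lower in 34 of 42, 0 called (2 with the replicate block, median -0.15, adjusted p = 0.00277, adjusted p = 0.700 with an estimated correlation). This call was lost without scramble replicate 1 (mean -0.02, adjusted p = 0.806) and without sh529 replicate 2 (-0.10, adjusted p = 0.0922). Cholesterol and fatty acid synthesis genes were lower in 25 of 31, 0 called (2 with the replicate block), led by the sterol oxidase MSMO1 (-0.77, adjusted p = 0.0664, 0.00217 with the replicate block). The cholesterol list (median -0.25, adjusted p = 0.000515, adjusted p = 0.659 with an estimated correlation) lost its call without scramble replicate 1 (mean -0.02, adjusted p = 0.647).

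In the other direction, 23 of 31 NF-kB and inflammatory cytokine genes were higher, 3 when adjusted over the list alone and 0 called over all genes (5 with the replicate block). Among them SOD2, the mitochondrial superoxide dismutase, stood at 1.22 (adjusted p = 0.0829, 0.000272 with the replicate block). The inflammatory list rose (median 0.33, adjusted p = 3.90e-05, adjusted p = 0.522 with an estimated correlation), but the 95% interval of its mean, 0.37, ran from -0.36 to 1.11. The mean itself ran from 0.21 to 0.54 over the alternatives and the fits without 1 array. That rise came from sh528, since with sh529 20 of 31 were lower (mean -0.21, adjusted p = 0.153). Mesenchymal and EMT genes rose, 18 of 25 higher and 0 called (3 higher and 2 lower with the replicate block, median 0.32, adjusted p = 0.00132, adjusted p = 0.559 with an estimated correlation), with fibronectin, FN1, at 1.09 (adjusted p = 0.160, 0.0143 with the replicate block). The 95% interval of the EMT list mean, 0.27, ran from -0.59 to 1.13, and without scramble replicate 1 the mean reversed to -0.001. Of 12 fibroblast marker genes on the array, 6 passed the detection filter. COL1A1 and POSTN passed with detection on 2 sh528 arrays and on 1 array of each other group. Of the 6 tested, 5 were higher (median 0.44, adjusted p = 0.00208, adjusted p = 0.447 with an estimated correlation). Of these DCN alone was called, and the list lost its call without scramble replicate 1 (mean 0.35, adjusted p = 0.244).

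**Figure D2:**
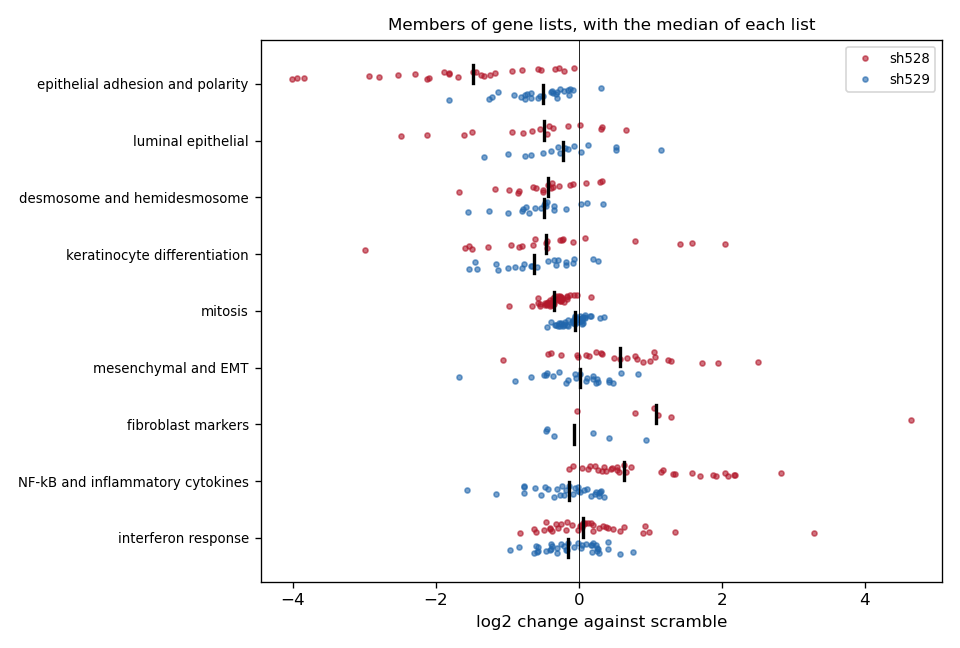
Log2 change against scramble of each member (points) of 9 gene lists with sh528 (red) and sh529 (blue), with the median as a black tick. The epithelial adhesion medians were -1.47 with sh528 and -0.50 with sh529.

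With sh528 alone, epithelial adhesion genes fell and NF-kB and inflammatory cytokine genes rose as lists (adjusted p = 0.129 and adjusted p = 0.359 with an estimated correlation). There were 101 genes higher and 89 lower (403 and 374 with the replicate block). DCN rose 25.0-fold (4.65 ± 0.21, adjusted p = 5.75e-06, 2.92 on its weakest probe) on both arrays. SAMSN1, an adaptor gene of immune cells, rose 16.2-fold (4.02 ± 0.38, adjusted p = 0.00134, detected on 1 of 2 scramble arrays, 1.91 on its other probe). IFI44L rose at least 7.25-fold (adjusted p = 0.00134). HSD17B2, which oxidizes estradiol, rose 8.95-fold (3.16, adjusted p = 0.0188, detected on 1 of 2 scramble arrays) and the leukotriene synthesis gene ALOX5AP 8.19-fold (3.03, adjusted p = 0.0191). CDH1 fell 16.2-fold (-4.02 ± 0.36, adjusted p = 0.00134), EPCAM 15.3-fold (-3.93 ± 0.43, adjusted p = 0.00271) and MAL2 14.4-fold (-3.84, adjusted p = 0.00230). S100P fell 7.95-fold (-2.99, adjusted p = 0.00116) and the membrane protease gene ST14 7.59-fold (-2.93, adjusted p = 0.00763, detected on 1 of 2 sh528 arrays). CD24 fell 4.37-fold (-2.13, adjusted p = 0.00297). The counts became 19 and 14 without scramble replicate 1 and 46 and 35 without scramble replicate 2. They became 39 and 39 without sh528 replicate 1 and 60 and 31 without sh528 replicate 2. Calls were lost for ALOX5AP, HSD17B2 and ST14 without scramble replicate 1, for HSD17B2 without sh528 replicate 1 and for ALOX5AP and HSD17B2 without sh528 replicate 2. The robust prior ended the calls of ALOX5AP and HSD17B2, and the fit without an intensity trend that of ALOX5AP.

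All 27 epithelial adhesion and polarity genes were lower with sh528, 15 of them called (median -1.47, adjusted p = 2.81e-30, adjusted p = 0.129 with an estimated correlation). CGN was no longer detected and at least 3.0-fold lower. NF-kB and inflammatory cytokine genes rose as a list, 29 of 31 being higher and 9 called (12 with the replicate block, median 0.63, adjusted p = 3.81e-12, adjusted p = 0.359 with an estimated correlation). Among them were SOD2 (2.09, adjusted p = 0.00572), the cytokine genes IL32 (1.93, adjusted p = 0.00572) and IL6 (1.70, adjusted p = 0.0326) and the acute-phase gene SAA2 (1.88, adjusted p = 0.0372). The mesenchymal and EMT list rose, 19 of 25 being higher and 3 called (10 higher and 1 lower with the replicate block, median 0.58, adjusted p = 2.26e-06, adjusted p = 0.453 with an estimated correlation). The 95% interval of the EMT list mean, 0.60, ran from -0.39 to 1.60. FN1 (1.94, adjusted p = 0.0123), the collagen cross-linking LOX (1.73, adjusted p = 0.0326) and the ligand WNT5A (2.51, adjusted p = 0.0123) were called. The extracellular matrix and integrin list rose, 23 of 38 being higher and 4 called (12 higher and 1 lower with the replicate block, median 0.15, adjusted p = 0.00765, adjusted p = 0.656 with an estimated correlation), but not without scramble replicate 1 (mean 0.10, adjusted p = 0.819). The interval of the matrix list mean, 0.34, ran from -0.30 to 0.97. DCN, the collagen COL12A1 (1.82, adjusted p = 0.0143) and the laminin LAMC1 (0.94, adjusted p = 0.0211) were called. Luminal genes were lower in 12 of 16, 3 called (6 lower and 1 higher with the replicate block, median -0.49, adjusted p = 1.00e-05, adjusted p = 0.168 with an estimated correlation). ALDH1A3 (-2.49, adjusted p = 0.00397) and FOXA1 (-1.61, adjusted p = 0.0141) were called. Desmosome genes were lower in 16 of 19, 0 called (5 with the replicate block, median -0.43, adjusted p = 0.000116, adjusted p = 0.359 with an estimated correlation) and keratinocyte differentiation genes in 17 of 22, 3 called lower and 2 higher (6 and 3 with the replicate block, median -0.45, adjusted p = 0.00124, adjusted p = 0.359 with an estimated correlation).

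With sh528 the mitosis list fell, 45 of 46 members being lower by little and 0 called (3 with the replicate block, median -0.35, adjusted p = 1.47e-08, adjusted p = 0.129 with an estimated correlation), with NUF2 at -0.97 (adjusted p = 0.0972, 0.00570 with the replicate block). The DNA replication list fell, 39 of 42 being lower and 0 called (5 with the replicate block, median -0.31, adjusted p = 1.75e-05, adjusted p = 0.556 with an estimated correlation), but not without scramble replicate 1 (mean -0.16, adjusted p = 0.0560). The ribonucleotide reductase RRM2 was at -0.73 (adjusted p = 0.231, 0.0123 with the replicate block). Among markers of other cell types, only the fibroblast list passed with sh528. Of these markers 5 of 6 were higher (median 1.08, adjusted p = 1.88e-05, adjusted p = 0.359 with an estimated correlation). Of the 12 markers fixed for this list, 10 are also in another list, such as EMT or matrix, so it is not separate evidence. DCN was the 1 called (4 with the replicate block), while POSTN (1.29, adjusted p = 0.0889, 0.00536 with the replicate block) and COL1A1 (0.78, adjusted p = 0.561) did not pass. Chosen after their values were seen, FAP of fibroblasts was at 1.11 (adjusted p = 0.0508, 0.000947 with the replicate block) and LAPTM5 of leukocytes rose at least 2.88-fold (1.66, adjusted p = 0.0141). CORO1A of leukocytes was lower (-1.13, adjusted p = 0.319), and the leukocyte (adjusted p = 0.402), endothelial (0.397), adipocyte (0.197) and keratinocyte marker lists (0.794) did not pass.

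With sh529 alone the same junction genes leaned lower, but only 1 gene was higher and 1 lower (57 and 84 with the replicate block), against 399 and 477 at an unadjusted p of 0.05. DYNLRB1 rose 2.86-fold on both arrays (1.52, adjusted p = 0.0381) and HES2 fell 4.47-fold on both (-2.16, adjusted p = 0.0381). In every fit that left out 1 array both genes missed the cutoff (adjusted p from 0.0606 to 0.319). Both also lost their calls with the mean of a gene's probes and in fits of only the groups compared, and DYNLRB1 without an intensity trend and with strict detection. The split was 0 higher and 1 lower with cyclic loess, without background correction and from the deposited matrix, and 2 higher and 4 lower with median scaling. CDH1 was 3.51-fold lower without passing (-1.81, adjusted p = 0.231, 0.000454 with the replicate block). Also lower without passing were PI3 (-1.54, adjusted p = 0.0872, 0.000104 with the replicate block), ALDH1A3 (-1.33, adjusted p = 0.302, 0.00613 with the replicate block) and KRT16 (-1.28, adjusted p = 0.0872, 0.00105 with the replicate block). CYP4V2 was at 2.14 (adjusted p = 0.0580, 0.000121 with the replicate block) and CD24 at -0.75 (adjusted p = 0.684).

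With sh529 no member of the lists named next was called over all genes. With the replicate block the numbers called lower were 2 (epithelial adhesion), 6 (keratinocyte differentiation), 3 (desmosome), 4 (basal), 2 (p53), 3 (retinoic acid) and 1 (cholesterol). Epithelial adhesion genes fell as a list, 26 of 27 being lower (median -0.50, adjusted p = 8.86e-10, adjusted p = 0.234 with an estimated correlation), such as CDH1 and CGN (-1.26, adjusted p = 0.389, 0.0345 with the replicate block). The 95% interval of their mean shift, -0.56, ran from -1.25 to 0.14. Keratinocyte differentiation genes were lower in 20 of 22 (median -0.62, adjusted p = 8.86e-10, adjusted p = 0.234 with an estimated correlation), with the protease KLK7 at -1.43 (adjusted p = 0.302, 0.0194 with the replicate block). Desmosome genes were lower in 16 of 19 (median -0.49, adjusted p = 2.36e-07, adjusted p = 0.234 with an estimated correlation), with the desmoplakin gene DSP at -0.99 (adjusted p = 0.302, 0.0137 with the replicate block). Basal genes, KRT16 among them, were lower in 18 of 23 (median -0.45, adjusted p = 4.75e-05, adjusted p = 0.239 with an estimated correlation). Target genes of p53 were lower in 25 of 32 (median -0.18, adjusted p = 0.000778, adjusted p = 0.234 with an estimated correlation). Retinoic acid response genes, with ALDH1A3 and HOXA5, were lower in 17 of 19 (median -0.19, adjusted p = 0.00107, adjusted p = 0.234 with an estimated correlation), and the list still passed without HOXA5 (mean -0.31, adjusted p = 0.00877, adjusted p = 0.256 with an estimated correlation). Cholesterol synthesis genes were lower in 27 of 31 (median -0.27, adjusted p = 0.000195, adjusted p = 0.828 with an estimated correlation), led by MSMO1 (-0.97, adjusted p = 0.111, 0.00313 with the replicate block). That call was lost without scramble replicate 1 (mean -0.05, adjusted p = 0.465) or sh529 replicate 2 (-0.06, adjusted p = 0.352). Inflammatory genes (median -0.14, adjusted p = 0.153), mitosis genes (-0.05, adjusted p = 0.240) and EMT genes (0.01, adjusted p = 0.927) did not pass with sh529.

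The 2 hairpins were also tested against each other: 50 genes were higher and 80 lower with sh529 than with sh528 (273 and 357 with the replicate block). Higher with sh529 were EPCAM (12.3-fold, 3.62 ± 0.43, adjusted p = 0.00513) and MAL2 (9.70-fold, 3.28, adjusted p = 0.00714). The growth factor carrier gene FGFBP1 (7.08-fold, 2.82, adjusted p = 0.00938), CDH1 (4.61-fold, 2.21, adjusted p = 0.0233) and CD24 (2.6-fold, 1.38, adjusted p = 0.0260) were higher too. IGFL1 of the insulin growth factor-like family (at least 7.74-fold, 3.30, adjusted p = 0.0132) and the kinase gene CAMK2B (at least 4.98-fold, 2.63, adjusted p = 0.0126, 0.36 on its weakest probe) were not detected with sh528. Lower with sh529 were SAMSN1 (17.6-fold, -4.14 ± 0.38, adjusted p = 0.00125), HSD17B2 (14.9-fold, -3.89, adjusted p = 0.00945) and DCN (13.0-fold, -3.70 ± 0.21, adjusted p = 5.89e-05, -2.92 on its weakest probe). So were the formyl peptide receptor gene FPR1 (13.2-fold, -3.72, adjusted p = 0.000603) and the transglutaminase gene TGM2 (9.60-fold, -3.26, adjusted p = 0.0259, -0.73 on its weakest probe). SAMSN1, HSD17B2 and FPR1 were detected on 1 of 2 sh529 arrays. Counts fell to 20 and 33 without sh528 replicate 1 and to 9 and 41 without sh528 replicate 2. They fell to 7 and 29 without sh529 replicate 1 and to 29 and 58 without sh529 replicate 2. CAMK2B lost its call in 3 of these fits, IGFL1 and TGM2 in 2 and HSD17B2 in 1. Calls were also lost for CAMK2B and TGM2 with the mean of a gene's probes, for TGM2 with the robust prior or without an intensity trend, and for IGFL1 without background correction and from the deposited matrix.

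By list, NF-kB and inflammatory cytokine genes were lower with sh529 than with sh528 in 30 of 31, 7 called (15 with the replicate block, median -1.12, adjusted p = 7.19e-16, adjusted p = 0.339 with an estimated correlation). Among them were SOD2 (-1.74, adjusted p = 0.0213) and IL32 (-2.27, adjusted p = 0.00384). Chosen after their values were seen, the alarmin genes S100A8 (-3.19, adjusted p = 0.000982) and S100A9 (-2.35, adjusted p = 0.00384) were lower too. Both are members of this list and of the keratinocyte differentiation list, so they add no separate evidence. Epithelial adhesion genes were higher with sh529 in 26 of 27, 8 called (14 with the replicate block, median 0.83, adjusted p = 5.29e-18, adjusted p = 0.255 with an estimated correlation), EPCAM, MAL2 and CDH1 among them. EMT genes, such as FN1 (-1.70, adjusted p = 0.0262) and WNT5A (-2.68, adjusted p = 0.0126), were lower in 22 of 25, 3 called (9 lower and 2 higher with the replicate block, median -0.58, adjusted p = 7.08e-08, adjusted p = 0.472 with an estimated correlation). Matrix genes were lower in 29 of 38, 3 called (10 with the replicate block, median -0.23, adjusted p = 1.27e-05, adjusted p = 0.593 with an estimated correlation). Fibroblast markers were lower in 6 of 6 (median -1.16, adjusted p = 3.51e-06, adjusted p = 0.339 with an estimated correlation), with FAP at -1.45 (adjusted p = 0.0213). Luminal genes were higher in 15 of 16, 1 called (4 with the replicate block, median 0.27, adjusted p = 0.000602, adjusted p = 0.316 with an estimated correlation), CD24 among them. Mitosis genes were higher in 45 of 46, 0 called (3 with the replicate block, median 0.25, adjusted p = 4.51e-06, adjusted p = 0.255 with an estimated correlation). Keratinocyte differentiation genes (median -0.002, adjusted p = 0.633) and desmosome genes (0.01, adjusted p = 0.689) did not shift in 1 direction between the hairpins, the latter with 0 members called (1 higher and 2 lower with the replicate block). Members of the keratinocyte differentiation list differed both ways, 1 called higher and 2 lower with sh529 (1 and 4 with the replicate block).

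**Figure D3:**
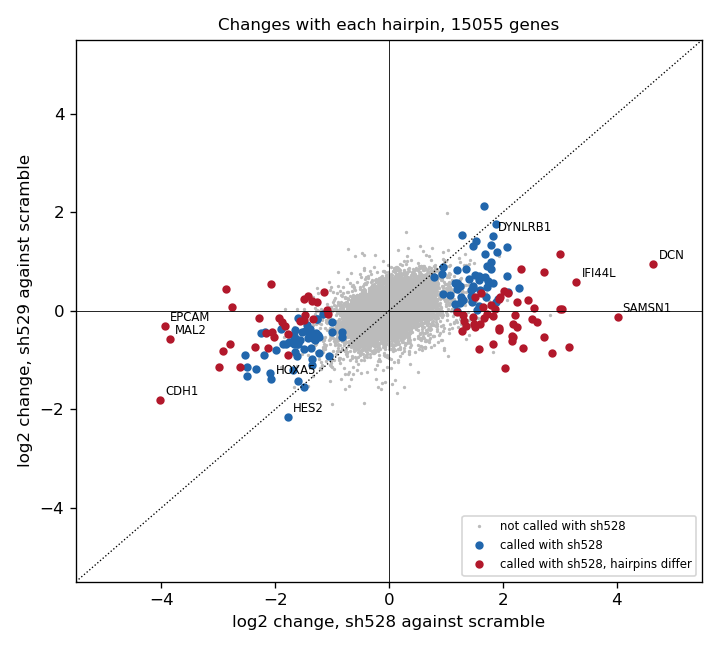
Log2 change with sh528 (horizontal) against log2 change with sh529 (vertical) for 15055 genes (points), with the dotted line at equal change. Blue points were called with sh528, red points also differed between the hairpins, and DCN lay at 4.65 and 0.95.

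DYNLRB1 (higher) and HES2 (lower) were the only genes called with each hairpin alone, 1 in each direction (37 and 33 with the replicate block). In all 6 fits without 1 array the numbers were 0 and 0. Independent lists would have shared 0.007 and 0.006, and 20 simulations with no change but the same shared scramble arrays gave at most 1 and 0. No gene changed with sh528 in these simulations. They therefore cannot say what overlap the shared arrays give where sh528 alone changes genes. Of the 101 genes higher with sh528, 70 (69.3%) were also above scramble with sh529, with medians of 1.73 and 0.28. Of the 101 genes 49 were called different between the hairpins (80 with the replicate block), DCN and SAMSN1 among them. Of the 89 lower genes, 80 (89.9%) were below scramble with sh529 (medians -1.62 and -0.53), among them CDH1 and HOXA5, and 32 were called different (69 with the replicate block), including EPCAM and MAL2. In simulations where sh528 changed its called genes by their observed size and sh529 changed nothing, the shared scramble arrays alone put 53.5% (higher) and 55.4% (lower) on the same side, with sh529 medians of 0.03 and -0.04. Sizes of called genes are inflated by the selection, so these no-change values are low. With no change with either hairpin and the same number of genes taken by p they were 93.0 and 91.6% (sh529 medians 0.39 and -0.38), but those genes moved less with sh528 (0.80 and -0.81), so these are high. How much of the observed shares is a response to sh529 was left open. Over all genes the 2 sets of changes correlated with r = 0.423, but both use the same 2 scramble arrays, which alone gave 0.499 in simulation. The covariance was 0.0555 against 0.0374 in simulation, an excess of 0.0181 (0.0273 and 0.0282 with the replicate block), and the SD over simulations was 0.0008. The simulations drew each gene independently, so this SD leaves out correlation between genes and does not measure the uncertainty of the excess. The excess was 0.0105 without sh529 replicate 2 and 0.0336 without scramble replicate 2. With each hairpin set against a different scramble array, so that no control was shared, r was 0.01 and 0.12 and the covariance 0.0023 and 0.0202 for the 2 ways of assigning them. Since arrays of equal replicate number resembled each other, these splits also carry the difference between numbers. The correlation was 0.536 and 0.591 without scramble replicate 1 or 2, where no change gave 0.668 and 0.666, and 0.308 without sh529 replicate 2, where no change gave 0.408.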

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

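The tests and bounds of the explanations weighed here were all chosen after the results were seen. Between the hairpins 50 genes were higher and 80 lower with sh529. Among single genes the differences (sh529 minus sh528, log2) were EPCAM 3.62, IGFL1 3.30, MAL2 3.28, FGFBP1 2.82, CAMK2B 2.63, SAMSN1 -4.14, HSD17B2 -3.89, FPR1 -3.72, DCN -3.70 and TGM2 -3.26. Lists that differed had mean log2 differences of 1.13 (epithelial adhesion), 0.47 (luminal), 0.28 (DNA replication), 0.27 (mitosis), 0.29 (unfolded protein and amino acid stress), -1.16 (NF-kB and inflammatory cytokines), -1.42 (fibroblast markers), -0.66 (EMT), -0.42 (extracellular matrix), -0.39 (TGF-beta response), -0.40 (histone genes), -0.31 (other HOX and TALE genes), -0.27 (interferon response) and -0.25 (hypoxia and glycolysis). With an estimated correlation 0 of these 14 lists stayed called, and with fry 0.

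Inflammatory genes such as SOD2 and IL32 were higher with sh528 (list mean 0.96, 95% interval 0.10 to 1.81, mean 0.63 without sh528 replicate 1). A deeper loss of HOXA5 could raise them, but the shift with sh529 was -0.21 (-1.06 to 0.64), which left that explanation open. An interferon response as large as the inflammatory one was argued against, since the interferon list moved less with sh528 (-0.79, interval -1.39 to -0.19). A smaller interferon response was left open, and the test cannot say whether it would raise inflammatory genes. With sh528 the interferon list had a mean of 0.17 (interval -0.26 to 0.59) and 22 of 37 members were higher. Of these 2 were called (5 with the replicate block), IFI44L among them. Leukocytes in the culture were argued against, with 2 of 14 leukocyte markers (CD14 and LAPTM5) detected on both sh528 arrays and PTPRC and CD53 on none. An effect of sh528 on another transcript could also lie behind the difference and was not tested.

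Epithelial adhesion genes such as CDH1 and CGN were lower over both hairpins, further with sh528 (list mean -1.68, 95% interval -2.37 to -0.99). The test of fibroblasts in the knockdown cultures used collagen genes, and these argued against them. Of COL1A1, COL1A2 and COL3A1 only 1 was detected on both sh528 arrays (COL1A1, at 5.16 and 5.97), while DCN stood at 13.7 and 13.5. Of all 12 fibroblast markers, 5 were detected on both sh528 arrays and 3 on both scramble arrays. LUM, PDGFRA, PDGFRB, THY1 and FBN1 were detected on no array. The 6 markers that passed the detection filter rose as a list with sh528 (mean 1.47, interval 0.02 to 2.93, 5 of 6 higher). Levels of different probes are not directly comparable, so fibroblasts were not excluded. Normalization was argued against, with -1.10 (interval -1.70 to -0.51) under cyclic loess and -1.06 (-1.73 to -0.39) under median scaling. The rest of the 5 other ways of making the values kept quantile normalization and changed the background step, offset or source of values. Their smallest fall was -0.76 (interval -1.14 to -0.37), and 2 of them gave the same numbers. A graded response to the depth of HOXA5 loss could not be told apart from an effect of 1 hairpin, with -0.56 with sh529 (-1.25 to 0.14). Selection of a subset of cells during stable transduction could give the same fall and was not tested.

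Arrays with the same replicate number resembled each other, and the lowest correlation of the replicate differences was 0.27. All arrays lay on 1 BeadChip, which argues against a separate hybridization for each number. A shared round of culture may cause the resemblance, and so may chance, and these cannot be told apart here.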

How the results depend on the processing

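Counts are given as higher/lower for both hairpins, sh528, sh529, sh529 minus sh528, and called with each hairpin alone, and the cause of each movement was not tested. At adjusted p of 0.01 they were 2/4, 30/24, 0/0, 6/21 and 0/0. The replicate block gave 185/218, 403/374, 57/84, 273/357 and 37/33, and its other changes are given beside the results they touch. Without the intensity trend they were 2/4 for both hairpins and 63/58 for sh528, with 0 higher for sh529, 27 higher between hairpins and 0 higher shared, and HOXA5 stayed at -1.72 with adjusted p = 0.0693. Probes detected on at least 1 array gave 30/39 (both), 4/10 (sh529), 76/129 (between hairpins) and 3/2 (shared). Strict detection on all arrays gave 10/10 (both), 32/51 (between hairpins) and 0 higher for sh529 and shared. No filter gave 27 higher (both), 4/10 (sh529) and 3/2 (shared). Cyclic loess, no background correction and the deposited matrix left 0 higher for sh529 and shared. Median scaling and the robust prior gave 2/4 for sh529 and 2 higher shared, and every probe on its own gave 2 higher for each. The mean of the probes, and fits of only the groups compared, gave 0/0 for sh529 and shared. Leaving out 1 array gave 1 to 26 higher and 0 to 29 lower (both), 19 to 130 and 14 to 104 (sh528), 0 and 0 to 1 (sh529), 7 to 41 and 29 to 75 (between hairpins), 0 and 0 (shared), a correlation of 0.308 to 0.591 and a HOXA5 log2 change, both hairpins against scramble, of -2.09 to -1.36. Of the list means, those of EMT over both hairpins (-0.0013 to 0.54) and cholesterol with sh528 (-0.44 to 0.0049) reversed without scramble replicate 1. Unfolded protein and amino acid stress over both (-0.56 to 0.17) and with sh528 (-0.70 to 0.027) reversed without scramble replicate 2. All 52 list calls were lost with an estimated correlation, and fry kept 8. These 8 were epithelial adhesion, luminal, retinoic acid response and mitosis, each over both hairpins and with sh528. With sh529 and between hairpins fry kept 0. The 95% interval of the list mean included 0 for many called lists. Over both hairpins these were HOXA, EMT, p53, DNA replication, inflammatory, cholesterol, stress, ribosomal and fibroblast lists. With sh528 they were HOXA, desmosome, EMT, TGF-beta, DNA replication, matrix, cholesterol and stress lists, and with sh529 epithelial adhesion and cholesterol. Between hairpins they were EMT, TGF-beta, DNA replication, interferon, matrix, hypoxia, stress and fibroblast lists. Strict detection ended the list calls of EMT (both hairpins), retinoic acid response (both hairpins and sh528), TGF-beta response and cholesterol synthesis (sh528). No background correction and the deposited matrix ended retinoic acid and TGF-beta response (sh528), offset 50 retinoic acid (sh528), median scaling TGF-beta (sh528), no filter fibroblast markers (both) and, like detection on at least 1 array, other HOX and TALE genes (between hairpins). The stress list between hairpins lost its call in 10 of 20 settings. A BeadChip block was not run, since all arrays lay on 1 BeadChip.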

Other observations

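Genes of NRF2 and xenobiotic response were not called as a list over both hairpins (median -0.03, adjusted p = 0.551), although AKR1C2 and the metallothionein MT1X (0.92, adjusted p = 0.0473) rose. AKR1C3 (1.20, adjusted p = 0.0628, 0.000140 with the replicate block) and CYP1B1 (1.69, adjusted p = 0.0794, 0.000370 with the replicate block) leaned the same way. Of the unfolded protein and amino acid stress list 24 of 33 were lower over both hairpins (median -0.14, adjusted p = 0.0137, adjusted p = 0.781 with an estimated correlation). With sh528 the amino acid transporter SLC7A5 (-0.82, adjusted p = 0.0338) and TRIB3 (-1.26, adjusted p = 0.0372) fell. That list lost its call without scramble replicate 2 (mean reversed to 0.17, adjusted p = 0.125), sh528 replicate 1 (-0.17, adjusted p = 0.0582) or sh529 replicate 1 (-0.10, adjusted p = 0.213). Targets of p53 were lower in 21 of 32 over both hairpins (median -0.12, adjusted p = 0.0154, adjusted p = 0.309 with an estimated correlation), SFN at -0.68 (adjusted p = 0.133, 0.00731 with the replicate block). The p53 call was lost without scramble replicate 2 (mean -0.16, adjusted p = 0.125), sh528 replicate 2 (-0.14, adjusted p = 0.0585) or sh529 replicate 1 (-0.15, adjusted p = 0.0788). Ribosomal protein genes were higher in 39 of 58 (median 0.07, adjusted p = 0.0341, adjusted p = 0.776 with an estimated correlation). This was lost without scramble replicate 2 (mean 0.06, adjusted p = 0.353), sh528 replicate 1 (0.08, adjusted p = 0.175) or sh529 replicate 1 (0.08, adjusted p = 0.213). Heat shock genes did not pass over both hairpins (median -0.14, adjusted p = 0.0755, 0.0416 with the replicate block) or with sh528 (-0.21, adjusted p = 0.0663, 0.0402 with the replicate block).

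Smaller calls with sh528 alone were retinoic acid response (median -0.13, adjusted p = 0.0300, 0.359 with an estimated correlation), HOXA cluster (-0.46, adjusted p = 0.00529, 0.536) and stress (-0.19, adjusted p = 0.00536, 0.656). Further ones were cholesterol synthesis (-0.25, adjusted p = 0.0171, 0.656) and TGF-beta response (0.21, adjusted p = 0.0392, 0.656). Without HOXA5 in the list neither retinoic acid response (adjusted p = 0.104) nor the HOXA cluster (0.0665) passed with sh528. Each of the 5 was lost in at least 1 fit without an array. Without scramble replicate 1 adjusted p was 0.0549 (retinoic acid), 0.108 (HOXA), 0.865 (cholesterol) and 0.819 (TGF-beta). Without scramble replicate 2 it was 0.898 (stress) and 0.0644 (retinoic acid). For the list HOXA cluster genes, sh528 against scramble, it was 0.0714 without sh528 replicate 1. Without sh528 replicate 2 it was 0.0943 (retinoic acid), 0.135 (cholesterol) and 0.636 (TGF-beta). Between the hairpins, TGF-beta response (median -0.36, adjusted p = 0.00155, 0.593 with an estimated correlation) and hypoxia and glycolysis (-0.18, adjusted p = 0.00483, 0.591) were lower with sh529. So were histone genes (-0.36, adjusted p = 0.00573, 0.472), interferon response (-0.09, adjusted p = 0.0122, 0.593) and other HOX and TALE genes (-0.21, adjusted p = 0.0131, 0.472). DNA replication (0.29, adjusted p = 0.000106, 0.608) and stress genes (0.16, adjusted p = 0.0423, 0.818) were higher with sh529. Single genes there were IFI44 (-1.66, adjusted p = 0.0231), the histone H2AC18 (-1.47, adjusted p = 0.0269) and the WNT antagonist SFRP1 (1.02, adjusted p = 0.0297). Without sh528 replicate 1 the interferon (adjusted p = 0.488), stress (0.238) and histone (0.118) calls were lost. Those of HOX and TALE (0.191) and TGF-beta (0.121) were lost without sh528 replicate 2. Without sh529 replicate 1 DNA replication (0.146), HOX and TALE (0.0692) and TGF-beta (0.0808) missed the cutoff, and without sh529 replicate 2 interferon (0.107), stress (0.583) and histone genes (0.0633) did. Hypoxia genes over both hairpins (adjusted p = 0.984) and interferon response (median -0.05, adjusted p = 0.984) did not pass, and neither did WNT, NOTCH or histone genes (adjusted p = 0.665 for each).

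Chosen after the data were seen, replicate 2 was compared with replicate 1 with the group in the model: 436 genes were higher and 270 lower. Unfolded protein and amino acid stress genes were higher in replicate 2 (mean 0.40, adjusted p = 2.75e-06, 0.663 with an estimated correlation), as were EMT (0.43, adjusted p = 6.36e-06, 0.573) and TGF-beta response genes (0.40, adjusted p = 0.000101, 0.573). Cholesterol synthesis (-0.34, adjusted p = 6.36e-06, 0.573) and epithelial adhesion genes (-0.29, adjusted p = 0.00278, 0.573) were lower. Other lists passed too. Higher were EGFR family (0.36, adjusted p = 0.000301), fibroblast (0.63, 0.00316), matrix (0.205, 0.00512) and mammary stem lists (0.28, 0.00612). Lower were DNA replication (-0.21, adjusted p = 0.000931), mitochondrial respiration (-0.14, 0.00914), interferon (-0.18, 0.0107), inflammatory (-0.19, 0.0401) and ribosomal lists (-0.11, 0.0447). Whether the numbers mark rounds of culture remained open. The lowest correlation between groups, 0.27, may reflect differences in cell density between rounds, which could be tested with counts of cells at harvest.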
